A study of Mus musculus with 8 samples.

How the data were processed

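RNA of 8 cultures of mouse bone marrow-derived macrophages had been hybridised to Illumina MouseRef-8 expression arrays, 1 array per culture. Cultures of 2 genotypes, LysMcre/+ (called LysMcre here) and scid with Atm c/c and LysMcre/+ (called ScidAtm here), were each profiled without infection and after infection with Listeria monocytogenes, with 2 independent cultures in each of the 4 groups. Group and replicate number came from the sample titles. The files name no slide, so no slide effect could be examined.

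The deposited non-normalized table gives, per the file headers and the values, 1 signal intensity and 1 detection p-value for each of 25697 probes on each array. The intensity values were neither background-subtracted nor scaled between arrays, with array medians between 112.543 and 162.233. Detection p-values fell in equal steps that imply 798 negative control beads per array. A second deposited table, the series matrix, holds intensity values that the authors had already processed. Each of its columns ranked the probes as the matching raw array did (rank correlation 1), between 7610 and 7641 of its values per array lay below 0, and every column shared the maximum of 49409.4. It was therefore read as background-subtracted and quantile-normalized on a linear scale, although the columns were not identical in distribution: 1 lowest value was -23.4 against -25.2 in the others, and the medians were 11.0, 11.0, 11.0, 10.9, 11.1, 11.1, 11.0 and 11.0. Its method of background subtraction is not given in the sources used here. GenomeStudio and Partek appear without version or role, per the submitters' processing notes.

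Background was corrected in limma 3.58.1 (R 4.3.3) with the normal-exponential model, estimated from the detection p-values in place of the control probes and with an offset of 16, and the arrays were quantile-normalized and taken to log2. Probes were named through GEO's platform annotation: 23978 had 1 gene symbol, 0 had several and 1719 had none, and 23962 of the named probes matched a current gene record by Entrez identifier, while 16 kept the file's name. A probe was kept if its detection p-value was under 0.05 on both arrays of at least 1 group. Of 11577 named probes that were kept, the brightest of each gene stood for it, which gave 8270 genes tested of 16593 on the array; 2305 of these had more than 1 probe. Among the genes called after infection that had more than 1 probe, 62 of 863 in LysMcre and 42 of 646 in ScidAtm had a probe of opposite sign, with an unadjusted p under 0.05 for 17 and 7 of them. Between 11214 and 12330 probes were detected per array (43.6% to 48.0%). The correlation of the 2 arrays of a group was 0.972, 0.986, 0.970 and 0.989 for LysMcre uninfected, LysMcre infected, ScidAtm uninfected and ScidAtm infected, and no probe had the same raw intensity on both arrays of a group.

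All 8 arrays were fitted in limma as 4 group means with empirical Bayes moderation, which left 4 residual degrees of freedom. The 6 comparisons were infection within each genotype, genotype within each treatment, the interaction (infection change in ScidAtm minus that in LysMcre) and the genotype difference averaged over treatments. P-values were adjusted by the Benjamini-Hochberg method over the 8270 genes, and a gene was called at an adjusted p under 0.05. Values written with ± are log2 changes with limma's standard error, and each group mean rests on n = 2 arrays, a number that limits the precision. Where a gene was not above background on either array of a group, its change is given as a bound, the mean of the brighter group against the mean over the dim group's arrays of the higher of the probe's own value and the lowest detected signal of the array. Coordinates are those of the mouse assembly GRCm38.p6, 1-based.

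A total of 23 gene lists had been fixed: p53 and DNA damage targets, double-strand break sensing and repair, type I interferon-stimulated genes, interferon-gamma-inducible GTPases and antigen presentation, NF-kB and inflammatory cytokines, inflammasome and pyroptosis, nitric oxide and reactive oxygen metabolism, cell cycle and DNA replication, migration and adhesion, macrophage identity and phagocytosis, lysosome, cholesterol synthesis, glycolysis and hypoxia response, mitochondrial respiration and TCA cycle, unfolded protein and integrated stress response, apoptosis and survival, and markers of lymphocytes, neutrophils, dendritic cells, erythroid cells and platelets, mast cells and basophils, fibroblasts and stroma, and sex. The 20 lists with at least 5 tested genes were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, were run as alternatives. The estimated correlation held no list call in any comparison, so failing it does not set 1 list apart from another. Counts of list members are given over all genes tested and adjusted over the list alone.

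Named genes follow a rule: the 10 largest rises and 10 largest falls that passed with non-overlapping arrays (or, with fewer than 10 calls, the 10 smallest p-values), up to 4 passing members per list and direction with the smallest adjusted p, up to 3 brightest members that did not pass, and a panel of 31 genes whatever their values. Unnamed gene models were passed over. The rule sets which genes may be named, and not all of them are printed. The tested panel genes Il6, Il10, Il18, Ccl2, Cd40 and Cd69 are among those left out. Of the panel, Trp53, Il12b and Ddx3y were not among the probes used here and Ifit1 was not detected on any array. The comparisons, tests, lists, naming rule and alternatives were set before the data were examined, except where a later choice is stated.

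The fit was tested on simulated data made from the real arrays, with 50 genes changed by each of log2 0.5, 1, 2 and 4 among 8270. It recovered 0%, 28%, 80% and 98% of them for infection in LysMcre, 0%, 18%, 68% and 92% in ScidAtm, 0%, 28%, 78% and 98% for genotype in infected cultures and 0%, 38%, 80% and 96% in uninfected cultures. False calls numbered 6 of 109, 3 of 92, 3 of 105 and 9 of 116. In the simulated data all other genes were unchanged between the groups compared, and the noise was independent between genes and arrays. The real infection comparisons called 35.5% of genes in LysMcre and 26.0% in ScidAtm, so these recovery rates do not describe them. False calls from a structure shared by arrays could not appear. Alternatives covered the background correction, median scaling in place of quantile normalization, an offset of 50, the series matrix values, the detection filter, the mean of a gene's probes, the variance model, the replicate number as a block, the groups in the fit, the thresholds and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.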

Results

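RNA was measured on 8 arrays, 2 independent cultures in each of 4 groups of bone marrow-derived macrophages. The cells had been grown from whole marrow of mice aged 4 to 8 weeks over 6 days in medium with 20% of the supernatant of L929 fibroblasts, which supplies the growth factor M-CSF. LysMcre cultures carried Cre recombinase expressed from the lysozyme M gene of myeloid cells and served as the control genotype. ScidAtm cultures carried in addition the scid mutation of Prkdc, which encodes the catalytic subunit of the DNA-dependent protein kinase, and Atm c/c alleles. Atm encodes the kinase that signals DNA double-strand breaks. The infected cultures received Listeria monocytogenes, an intracellular Gram-positive bacterium, at a multiplicity of 5 and were taken at 24 h. The labels give the uninfected cultures a time of 0 h, so each infection comparison also spans 24 h of culture. The series asks which part of the macrophage programme after infection involves signalling from DNA damage.

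The targeted genes were read on every array first. Atm stood at a normalized log2 signal of 7.30 and 7.82 in uninfected LysMcre cultures 1 and 2 and at 6.83 and 6.63 in the infected ones. In ScidAtm it stood at 4.92 and 4.97 without infection and at 5.38 and 4.94 with it, and was detected on 1 of 2 arrays of each group. A further Atm probe gave 6.60, 6.91, 6.28 and 5.56 on the same LysMcre arrays and 4.80, 5.06, 4.54 and 4.65 on the ScidAtm arrays, and the last Atm probe was not detected on any array. Prkdc lay near background everywhere, at 5.15, 5.54, 4.47 and 4.77 in LysMcre and at 4.81, 5.07, 4.75 and 4.67 in ScidAtm. A further Prkdc probe gave 4.67, 5.67, 4.51 and 4.40 in LysMcre and 5.10, 5.45, 4.69 and 4.38 in ScidAtm. Each of these probes was detected on 3 arrays, all of them uninfected. Averaged over treatments Prkdc, read from the first probe, did not differ between genotypes past the threshold (limma, adjusted p = 0.999). Which exon the probes cover is not known here, and a probe outside the deleted or mutated part need not reflect the alleles. Xist, transcribed from the inactive X chromosome of female cells, stood at 4.43 and 4.66 on the uninfected and infected LysMcre arrays numbered 2 and between 8.99 and 9.61 on the other 6. The Y-linked gene Eif2s3y, read after Xist had been seen, stood at 9.42 and 9.37 on those 2 arrays and at 4.98 or less on the others. The LysMcre group thus mixed the sexes and the ScidAtm group did not.

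In LysMcre macrophages Lcn2, whose product binds bacterial siderophores, was at least 369-fold higher after infection (limma with Benjamini-Hochberg adjustment, adjusted p = 1.21e-05, n = 2 per group). The chemokine genes Ccl5 and Ccl12 rose by log2 7.77 ± 0.19 and 7.46 ± 0.56, and the interferon-stimulated genes Oasl1 and Slfn1 by 8.14 ± 0.79 and 7.55 ± 0.90. Among the genes that fell, the thymidine kinase gene Tk1 was at least 82.5-fold lower and the topoisomerase gene Top2a at least 64.9-fold lower. The PCNA-associated factor Pclaf was at least 70.2-fold lower (adjusted p = 1.47e-05). In all, 1254 genes rose and 1680 fell of 8270 tested (35.5% called), 869 and 1171 of them by at least 2-fold.

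Among the panel of genes fixed for all comparisons, the inducible nitric oxide synthase gene Nos2 and the interferon-beta gene Ifnb1 were not above background without infection. They were at least 30.2-fold and 31-fold higher with it (adjusted p = 1.47e-05 and 3.72e-05). Arg1, an arginase, rose by 6.76 ± 0.35, Il1b by 6.70 ± 0.51, Tnf by 3.39 ± 0.67 and Isg15, a ubiquitin-like interferon-stimulated protein, by 6.04 ± 0.80. Il1a was at least 42.6-fold higher. Casp1 and Casp4, the inflammatory caspases, rose by 1.52 ± 0.24 and 3.11 ± 0.27. The sensors Aim2 and Nlrp3, the lysozyme gene Lyz2 and the control genes Actb and Gapdh did not pass. Lyz2 was read from its brightest probe, at 15.329 and 15.242 without infection and 15.113 and 14.655 with it. Its other probes, not used in this test, went from 14.29 and 14.027 to 13.471 and 13.023 and from 6.687 and 6.195 to 6.175 and 4.767. The p53 target Cdkn1a stood at 1.19 (adjusted p = 0.0953, or 0.0499 without either ScidAtm uninfected array).

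All 36 tested type I interferon-stimulated genes rose, among them Ifi205 (at least 52-fold), Mx1 (at least 67.3-fold) and Isg20 (5.82 ± 0.39). The list stood above other genes (camera adjusted p = 7.6e-20; adjusted p = 0.276 with an estimated correlation). Of 30 interferon-gamma-inducible GTPases and antigen presentation genes, 23 rose, 0 fell and 7 did not pass, with Gbp2 at 6.00 ± 0.38 and Gbp3 at 5.54 ± 0.37. Adjusted over the list alone, 23 were higher and 1 lower, H2-DMa (-0.59 ± 0.23), and the list's adjusted p was 3.27e-11 (adjusted p = 0.306 with an estimated correlation). NF-kB and inflammatory cytokine genes rose in 37 of 40 cases, 38 when adjusted over the list alone, among them the adaptor Traf1 (4.10 ± 0.18). That list had an adjusted p of 7.6e-20, and adjusted p = 0.111 with an estimated correlation.

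The inflammasome and pyroptosis list had 10 members higher, 1 lower and 6 not passing, or 11 higher and 1 lower adjusted over the list alone (adjusted p = 0.000191; adjusted p = 0.111 with an estimated correlation). Mefv, the pyrin gene, rose by 3.21 ± 0.22. In the nitric oxide and reactive oxygen list, 9 of 24 genes rose and 1 fell, 10 and 1 adjusted over the list alone (adjusted p = 0.000633; adjusted p = 0.111 with an estimated correlation). Ass1, which resupplies arginine, rose by 4.32 ± 0.29 and the superoxide dismutase gene Sod1 fell by 1.03. Apoptosis and survival genes rose in 12 of 25 cases and fell in 2, the same counts as adjusted over the list alone (adjusted p = 0.000993; adjusted p = 0.111 with an estimated correlation). They included the necroptosis effector Mlkl (3.51 ± 0.24) and Gadd45b (3.37 ± 0.27). The unfolded protein and integrated stress response list had 11 of 27 members higher and 4 lower, and Slc7a5 (-1.74 ± 0.62) was a further one lower adjusted over the list alone. Over all genes Slc7a5 passed under median scaling (adjusted p = 0.0149) and with only the groups compared in the fit (0.0465). The stress factors Ddit3 and Nupr1 rose by 4.57 ± 0.34 and 4.32 ± 0.28 while the serine synthesis gene Psat1 fell by 3.15. This list's adjusted p was 0.0248, with adjusted p = 0.165 with an estimated correlation and 0.063 without LysMcre infected array 1.

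The cell cycle and DNA replication list fell in 27 of 31 cases, 28 when adjusted over the list alone (camera adjusted p = 8.09e-17; adjusted p = 0.131 with an estimated correlation). Nusap1, a spindle protein gene, stood at -5.25 ± 0.23 and the microtubule regulator Stmn1 at least 16.4-fold lower, while Pcna did not pass. Of 20 double-strand break sensing and repair genes, 11 fell and 9 did not pass, also when adjusted over the list alone (adjusted p = 0.000357; adjusted p = 0.306 with an estimated correlation). Among them were the histone variant gene H2ax (-2.94 ± 0.19), the helicase gene Blm (-3.06 ± 0.28) and the recombination gene Rad54l (-4.61 ± 0.47). Cholesterol synthesis genes fell in 10 of 18 cases, 13 adjusted over the list alone (adjusted p = 0.000357; adjusted p = 0.364 with an estimated correlation). The sterol carrier Stard4 stood at -3.95 ± 0.44 and Fdps at -2.60 ± 0.29. In the mitochondrial respiration and TCA cycle list 11 of 31 genes fell, also when adjusted over the list alone (adjusted p = 0.00199; adjusted p = 0.313 with an estimated correlation). Idh3a fell by 2.05 and Fh1 by 1.69.

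Several lists held members that moved apart and were not called by camera. Of 29 macrophage identity and phagocytosis genes 10 rose and 8 fell, 10 and 10 adjusted over the list alone (adjusted p = 0.368). The scavenger receptor Marco rose by 4.52 ± 0.34 and the Fc receptor Fcgr4 by 3.32 ± 0.24, while the mannose receptor Mrc1 fell by 4.41 and Trem2 by 1.59. Migration and adhesion genes split 9 higher and 6 lower of 26, 10 and 6 adjusted over the list alone (adjusted p = 0.168). The formyl peptide receptor Fpr2 rose by 6.45 ± 0.36 and the fractalkine receptor Cx3cr1 fell by 5.51. The p53 and DNA damage targets had 4 of 26 higher and 4 lower by either adjustment and a median of 0.13, or -0.17 under median scaling (adjusted p = 0.461), with Fas at 2.49 ± 0.23 and Plk2 at 2.19 ± 0.25. Lysosome genes stood at 6 higher and 3 lower of 31 by either adjustment (adjusted p = 0.0657), with Gla at 1.70 ± 0.32 and Gusb at -1.18 ± 0.18. Glycolysis and hypoxia genes stood at 5 higher and 3 lower of 25, 6 and 3 adjusted over the list alone (adjusted p = 0.37), with Hk3 at 2.25 ± 0.29 and Aldoc at -2.13 ± 0.29.

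Markers of other cells also moved with infection, with the same counts when adjusted over the list alone. Fibroblast and stromal markers rose in 3 of 5 cases, with the matrix genes Dcn and Lox at least 14.2-fold and 14.1-fold higher (list adjusted p = 0.0178; adjusted p = 0.165 with an estimated correlation). Neutrophil and granule markers stood at 2 higher, haptoglobin Hp (5.59 ± 0.37) and S100a8 (2.58 ± 0.23), and 1 lower of 8 (adjusted p = 0.37). Dendritic cell markers stood at 1 higher, Bst1 (3.89 ± 0.26), and 2 lower of 5, among them the langerin gene Cd207 at least 39.7-fold lower (adjusted p = 0.51). Erythroid and platelet markers stood at 1 higher and 2 lower of 5, with Tfrc at -1.45 ± 0.27 (adjusted p = 0.441). The only tested mast cell and basophil marker, the histidine decarboxylase gene Hdc, rose by 3.95 ± 0.19. Of 2 lymphocyte markers 1 fell, and the only tested sex-linked gene, Xist, did not pass.

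The number of calls rested on single arrays: it was 1528 without LysMcre infected array 2. Leaving out both LysMcre arrays numbered 2, in which Xist was not detected, kept 1 LysMcre array per treatment. Cx3cr1, Casp1 and Tnf were then among the genes that no longer passed, at changes of -3.58, 1.44 and 2.66. Median scaling in place of quantile normalization gave 852 genes higher and 1844 lower (31.6% of calls higher, against 42.7%). It moved the median of all genes to -0.18 in this comparison and to -0.23, 0.22, 0.27 and 0.25 for infection in ScidAtm and for genotype in infected cultures, in uninfected cultures and averaged.

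**Figure D1:**
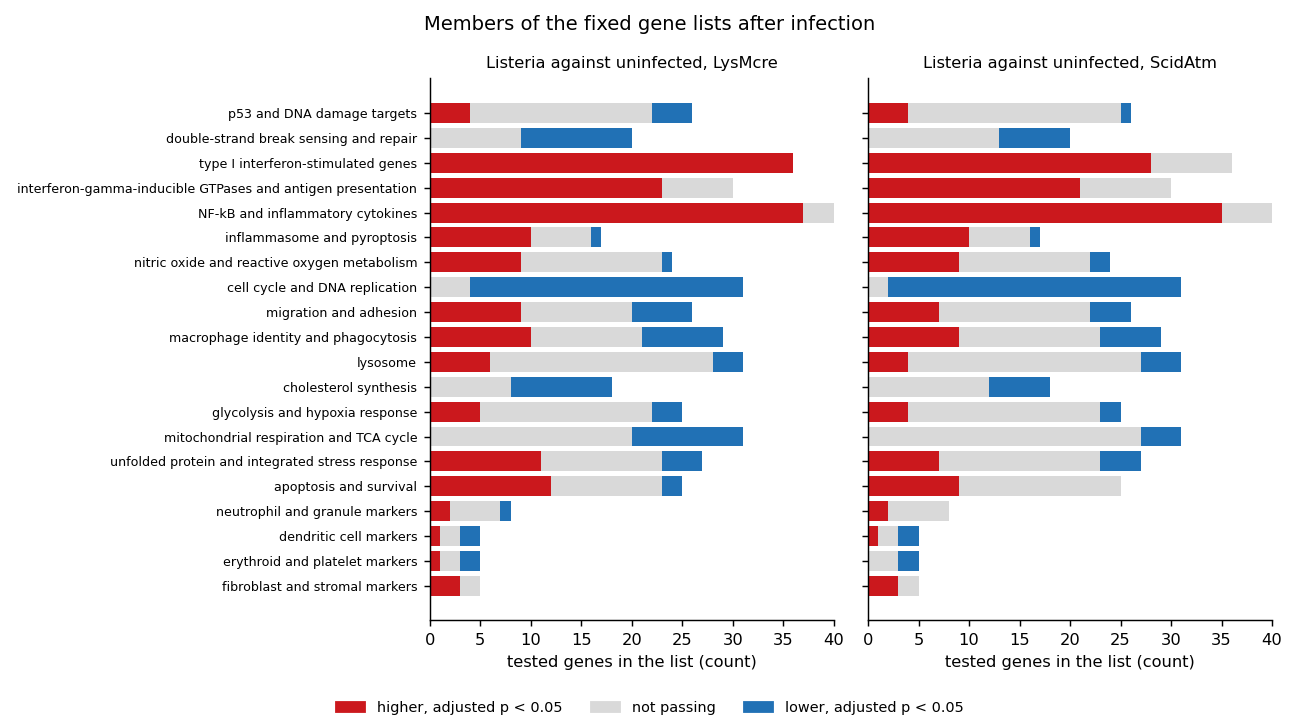
Counts of members of each fixed list with at least 5 tested genes after infection, in LysMcre (left) and ScidAtm (right). The horizontal axis counts genes, red marks members higher and blue members lower at an adjusted p under 0.05 (limma, n = 2 arrays per group), and grey marks members that did not pass; all 36 interferon-stimulated genes are red in LysMcre and 28 in ScidAtm.

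In ScidAtm macrophages Lcn2 rose after infection by 9.45 ± 0.32, Il1b by 7.37 ± 0.51 and the chemokine genes Cxcl9 and Ccl5 by 7.27 ± 0.42 and 6.90 ± 0.19 (limma with Benjamini-Hochberg adjustment, adjusted p = 7.75e-06, 0.000124, 5.94e-05 and 4.49e-06, n = 2 per group). The complement factor gene Cfb was at least 97.8-fold higher. The mitotic kinase gene Pbk fell by 6.41, Tk1 by 5.71 and Birc5, which encodes survivin, by 5.48, and Cd207 was at least 35.6-fold lower. A total of 979 genes rose and 1175 fell (26.0% called), 668 and 828 of them by at least 2-fold.

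Of the panel, Nos2 was at least 13.3-fold and Ifnb1 at least 5.47-fold higher in infected ScidAtm cultures (adjusted p = 6.16e-05 and 0.000722). Arg1 rose by 6.27 ± 0.35, Casp1 by 1.54 ± 0.24 and Casp4 by 2.68 ± 0.27. Isg15 rose by 3.27 ± 0.80 (adjusted p = 0.0218, or 0.0544 with no detection filter). Its call ended without ScidAtm uninfected array 1 (0.0963), infected array 1 (0.11) or infected array 2 (0.0857). Tnf stood at 2.02 (adjusted p = 0.0607) and Mdm2 at 0.77 (adjusted p = 0.0919). Neither passed, although Tnf did without LysMcre uninfected array 1 or array 2 (0.0175 each), under median scaling (0.0405) and with only the groups compared in the fit (0.035).

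Among the lists, type I interferon-stimulated genes rose in 28 of 36 cases, 34 adjusted over the list alone (camera adjusted p = 3.29e-14; adjusted p = 0.332 with an estimated correlation). Ifi205 rose by 5.56 ± 0.21, Mx1 by 4.40 ± 0.42 and Zbp1 by 3.20 ± 0.24. Interferon-gamma-inducible genes rose in 21 of 30 cases by either adjustment, with Gbp2 at 4.17 ± 0.38 (adjusted p = 1.71e-10; adjusted p = 0.332 with an estimated correlation). NF-kB and inflammatory cytokine genes rose in 35 of 40 cases, 37 adjusted over the list alone, with Traf1 at 3.95 ± 0.18 (adjusted p = 2.17e-21; adjusted p = 0.0985 with an estimated correlation). Inflammasome genes had 10 higher and 1 lower of 17 by either adjustment, with Mefv at 3.21 ± 0.22 (adjusted p = 0.000101; adjusted p = 0.0985 with an estimated correlation). Nitric oxide and reactive oxygen genes had 9 higher and 2 lower of 24, 11 and 2 adjusted over the list alone, with Ass1 at 4.14 ± 0.29 (adjusted p = 0.00108; adjusted p = 0.0985 with an estimated correlation). Apoptosis genes had 9 higher of 25, 10 adjusted over the list alone, with Mlkl at 2.54 ± 0.24 (adjusted p = 0.00402; adjusted p = 0.0985 with an estimated correlation).

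Cell cycle genes fell in 29 of 31 cases in ScidAtm, 31 adjusted over the list alone, with Nusap1 at -5.01 ± 0.23 (adjusted p = 2.17e-21; adjusted p = 0.0985 with an estimated correlation). Double-strand break genes fell in 7 of 20 cases, with H2ax at -2.29 ± 0.19 (adjusted p = 0.00729; adjusted p = 0.383 with an estimated correlation). Adjusted over the list alone, 7 were lower and 1 higher, the end-joining gene Xrcc4 (0.58 ± 0.18). Over all genes Xrcc4 did not pass in the reported fit. It did with no background correction (adjusted p = 0.0354), an offset of 50 (0.0407) and the mean of probes (0.0472). It also did with no detection filter (0.0314) and with a detection p under 0.01 (0.0441). Cholesterol synthesis genes fell in 6 of 18 cases, 13 adjusted over the list alone, with Stard4 at -3.58 ± 0.44 (adjusted p = 5.29e-05; adjusted p = 0.332 with an estimated correlation). Respiration genes fell in 4 of 31 cases by either adjustment, with Idh3a at -1.92 ± 0.21 (adjusted p = 0.00864; adjusted p = 0.372 with an estimated correlation).

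Camera did not call the other lists in ScidAtm. The unfolded protein list had 7 higher and 4 lower of 27, 8 and 4 adjusted over the list alone (adjusted p = 0.076), with Nupr1 at 4.03 ± 0.28 and Psat1 at -3.08 ± 0.22. Macrophage identity genes had 9 and 6 of 29, 10 and 6 adjusted over the list alone (adjusted p = 0.603), and Marco was at least 5.91-fold higher while Mrc1 fell by 4.23. Migration genes had 7 and 4 of 26, 8 and 4 adjusted over the list alone (adjusted p = 0.542), with Fpr2 at 7.13 ± 0.36 and Plau at -3.63 ± 0.42. Camera placed both of these lists higher although their medians were -0.10 and -0.08, with means of 0.18 and 0.47. The p53 targets had 4 higher and 1 lower of 26 (Fas 3.13 ± 0.23; adjusted p = 0.325), lysosome genes 4 and 4 of 31 (adjusted p = 0.43) and glycolysis genes 4 and 2 of 25 (adjusted p = 0.987), all by either adjustment. Fibroblast and stromal markers again had 3 of 5 higher (adjusted p = 0.0553), with Dcn at least 19.3-fold and Lox at least 13.2-fold. Neutrophil markers had 2 of 8 higher (adjusted p = 0.306), erythroid markers 2 of 5 lower (adjusted p = 0.0933), and dendritic cell markers 1 higher and 2 lower of 5, 1 and 3 adjusted over the list alone (adjusted p = 0.44). S100a8 rose by 3.67 ± 0.23, Tfrc fell by 1.78 and Hdc rose by 2.58 ± 0.19. Of 2 lymphocyte markers 0 passed, and Xist did not pass.

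In fry, all 12 lists called in LysMcre and all 10 called in ScidAtm passed. The 2154 calls in ScidAtm fell to 921 without ScidAtm infected array 1 and to 978 without infected array 2. Median scaling gave 579 genes higher and 1692 lower there (25.5% higher, against 45.5%).

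Set side by side, the infection responses ran in the same direction with smaller changes in ScidAtm, and they share no array. A total of 791 genes rose in both genotypes and 1061 fell in both, 0 were called in opposite directions, 1082 were called in LysMcre alone and 302 in ScidAtm alone. The log2 changes correlated at r = 0.938 across genes, which are not independent replicates. Over the 2934 genes called in LysMcre, the slope of the ScidAtm change on the LysMcre change was 0.803. The median rise was 1.04 in ScidAtm against 1.30 in LysMcre, and the median fall -0.98 against -1.26, with median differences per gene of -0.32 and 0.32. Genes picked by their change in LysMcre tend to show a smaller change elsewhere, so the slope was also taken over the 2154 genes called in ScidAtm, where it was 0.850, and over those called in both, 0.842. In the genes called in ScidAtm the median rise was 1.26 against 1.40 and the median fall -1.28 against -1.44, with median differences per gene of -0.08 and 0.19. Single cultures were also used, with infected and uninfected cultures of a genotype matched by replicate number. The 4 combinations of the genotypes gave 0.877, 0.762, 0.783 and 0.724 (SD 0.0654). Other matchings of cultures were not run, and the 4 values share arrays, so this SD need not give the full spread. By list the slope was 0.619 for the 36 type I interferon-stimulated genes, 0.883 for NF-kB genes, 0.858 for cell cycle genes and 0.976 for migration genes.

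**Figure D2:**
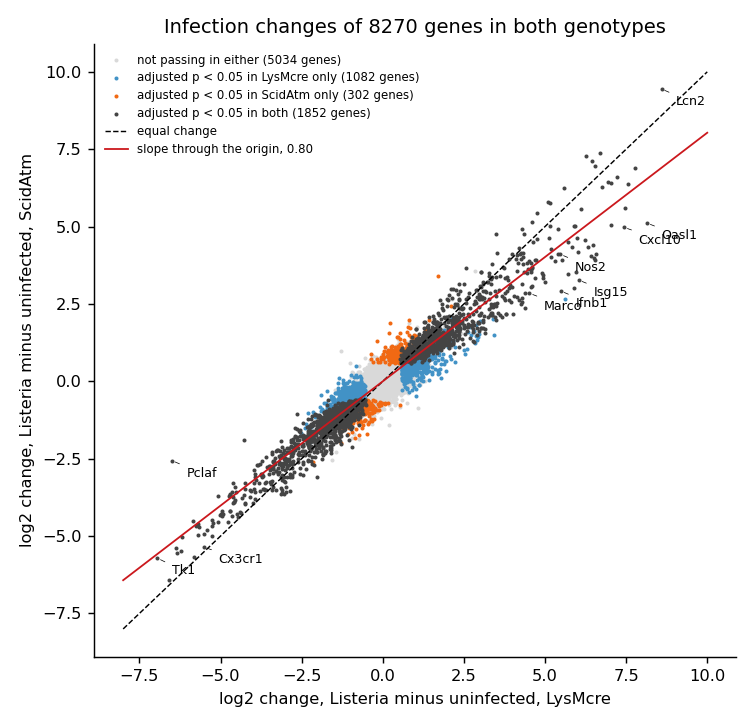
Log2 change after infection in LysMcre (horizontal) against ScidAtm (vertical) for 8270 genes, 1 point per gene, coloured by whether limma's adjusted p was under 0.05 in 1, both or neither genotype. The dashed line marks equal change and the red line the slope of 0.803; Isg15, Cxcl10 and Ifnb1 lie below the dashed line.

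Tested gene by gene, the difference between the infection changes passed for no gene. Pclaf had the smallest p (limma interaction with Benjamini-Hochberg adjustment, adjusted p = 0.0711, n = 2 per group, and 0.044 without LysMcre uninfected array 1). It was not above background on any infected array, so this difference has no exact size and restates that between the uninfected cultures. The heat shock gene Hspa1a stood at -1.77 ± 0.27 and the chemokine gene Ccl3 at -1.71 ± 0.31 (adjusted p = 0.8 each). Isg15 and Cxcl10 stood at -2.77 ± 1.13 and -2.46 ± 1.08 (adjusted p = 0.997 each). Ifnb1 (adjusted p = 0.8) and Nos2 (adjusted p = 0.997) were not above background in uninfected cultures of either genotype, so their interaction restates the difference between the infected cultures. limma called 0 of 8270 genes, with 343 at an unadjusted p under 0.05 against 413.5 by chance.

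At the level of lists, camera placed type I interferon-stimulated genes lower in the interaction, with all 36 values negative and a median of -1.53 (adjusted p = 3.62e-24; adjusted p = 0.405 with an estimated correlation). Also placed lower were interferon-gamma-inducible genes, 25 of 30 negative (adjusted p = 7.35e-05; adjusted p = 0.495 with an estimated correlation), and NF-kB genes, 27 of 40 negative (adjusted p = 0.000902; adjusted p = 0.405 with an estimated correlation). Apoptosis genes, 16 of 25 negative, went the same way (adjusted p = 0.024; adjusted p = 0.405 with an estimated correlation). So did lysosome genes, 20 of 31 negative (adjusted p = 0.0278; adjusted p = 0.567 with an estimated correlation), and migration genes, 18 of 26 negative (adjusted p = 0.0422; adjusted p = 0.412 with an estimated correlation). Double-strand break genes, 18 of 20 positive, were placed higher (adjusted p = 0.00156; adjusted p = 0.405 with an estimated correlation), as were cell cycle genes, 25 of 31 positive (adjusted p = 0.0155; adjusted p = 0.524 with an estimated correlation). No member of these 8 lists passed over all genes. Adjusted over the list alone, the NF-kB genes Csf3 (1.23 ± 0.27) and Ccl3 passed, 1 higher and 1 lower, and 0 members of the other 7 lists did. Fry called none of the 8. By the list means per array, the interactions of both interferon lists and of cell cycle and double-strand break genes came mainly from the uninfected cultures. The NF-kB interaction came mainly from the infected cultures.

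Of these list results the type I interferon one held without each array in turn. The interferon-gamma list lost its call without ScidAtm uninfected array 2 (0.338). The NF-kB and double-strand break lists lost theirs without LysMcre uninfected array 2 (0.206 and 0.287) or ScidAtm uninfected array 1 (0.154 and 0.0979). The cell cycle list did without those arrays (0.563 and 0.199) or LysMcre infected array 2 (0.104). For the apoptosis list the arrays were LysMcre uninfected 1 (0.0549) and infected 2 (0.104), ScidAtm uninfected 1 (0.131) and infected 2 (0.0927). The lysosome list turned its direction without LysMcre uninfected array 2 (0.772). Its call also ended without LysMcre infected 2 (0.104), ScidAtm uninfected 1 (0.0979) or 2 (0.0733) or ScidAtm infected 1 (0.0755). The migration list lost its call without LysMcre uninfected 2 (0.563) or infected 2 (0.168), ScidAtm uninfected 1 (0.0979) or 2 (0.118) or ScidAtm infected 1 (0.0501) or 2 (0.0888).

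Uninfected ScidAtm and LysMcre macrophages differed in 3 genes. Atm was lower in ScidAtm by a log2 difference of -2.62 ± 0.25 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0307, n = 2 per group). Pclaf was lower as well (-4.29 ± 0.27, adjusted p = 0.00286), and Clec16a, a gene of mitophagy and autophagy, was higher by 1.89 ± 0.20 (adjusted p = 0.0426). Next by p came Mns1 (-2.52 ± 0.29, adjusted p = 0.0541) and the kinesin gene Kif23 (-1.38 ± 0.19, adjusted p = 0.184), and neither passed. With an offset of 50 Mns1 did (adjusted p = 0.0450). Also short of passing were the phosphatase subunit gene Ppp2r1b (2.30 ± 0.38, adjusted p = 0.467), Ccl5 (0.99 ± 0.19, adjusted p = 0.958) and Ifi204, a DNA sensor gene (1.59 ± 0.32, adjusted p = 0.999). In all, 324 genes had an unadjusted p under 0.05, against 413.5 by chance. Same-numbered uninfected cultures deviated together (r = 0.581 across genes), and this fit left that structure in its residual spread. With the replicate number as a block within each treatment, chosen after seeing the data, more genes passed, as given in the part on processing. The counts here therefore do not show how little the genotypes differ. Atm lost its call without each of the 8 arrays in turn (adjusted p between 0.0622 and 0.381), as did Clec16a (between 0.109 and 0.473). Pclaf lost it without ScidAtm uninfected array 2, at a difference of -4.15, and with the mean of all its probes in place of the brightest Clec16a had an adjusted p of 1.00. Clec16a also lost its call with an offset of 50 (adjusted p = 0.0533), with the series matrix values (0.0584) and with the alternative variance model (0.102).

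Type I interferon-stimulated genes were placed higher in uninfected ScidAtm cultures, with 35 of 36 values positive and a median of 1.33 (camera adjusted p = 5.4e-29; adjusted p = 0.555 with an estimated correlation). No member passed over all genes, and 1 did adjusted over the list alone, Ifi204. Isg15 stood at 2.25 ± 0.80 (adjusted p = 0.999). In a limma fit chosen after seeing the data, with the replicate number as a block within each treatment, its adjusted p was 0.0113. Relative to each gene's mean, the list stood at -3.05 and -1.77 in uninfected LysMcre cultures 1 and 2 and at -1.69 and -0.35 in ScidAtm cultures 1 and 2. The higher LysMcre value, of culture 2, thus lay close to the lower ScidAtm value, of culture 1. Between cultures of the same number ScidAtm lay higher by 1.35 and 1.42, although no label says that a number marks a shared preparation. Interferon-gamma-inducible genes were positive in 24 of 30 cases with a median of 0.32 (adjusted p = 2.36e-07; adjusted p = 0.6 with an estimated correlation), a call lost without ScidAtm uninfected array 2 (0.527). Macrophage identity genes were positive in 18 of 29 cases with a median of 0.08 (adjusted p = 0.00854; adjusted p = 0.555 with an estimated correlation). That call ended without LysMcre uninfected array 2 (0.273) or ScidAtm uninfected array 1 (0.0706) or 2 (0.0593). Cell cycle genes were negative in 26 of 31 cases with a median of -0.45 (adjusted p = 5.05e-06; adjusted p = 0.555 with an estimated correlation), lost without LysMcre uninfected array 2 (0.293) or ScidAtm uninfected array 1 (0.0706). Double-strand break genes were negative in 16 of 20 cases with a median of -0.30, or 0.04 under median scaling (adjusted p = 3.29e-05; adjusted p = 0.555 with an estimated correlation). Atm was their only member that passed, and the call ended without the same arrays (0.293 and 0.0925). The double-strand break list holds Atm and Prkdc, the genes altered in ScidAtm, and was not tested without them. Its placement between genotypes thus partly reflects Atm itself. No member of the interferon-gamma, macrophage identity and cell cycle lists passed, over all genes or adjusted over the list alone. The other 15 lists were not called, and fry called none of the 5.

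**Figure D3:**
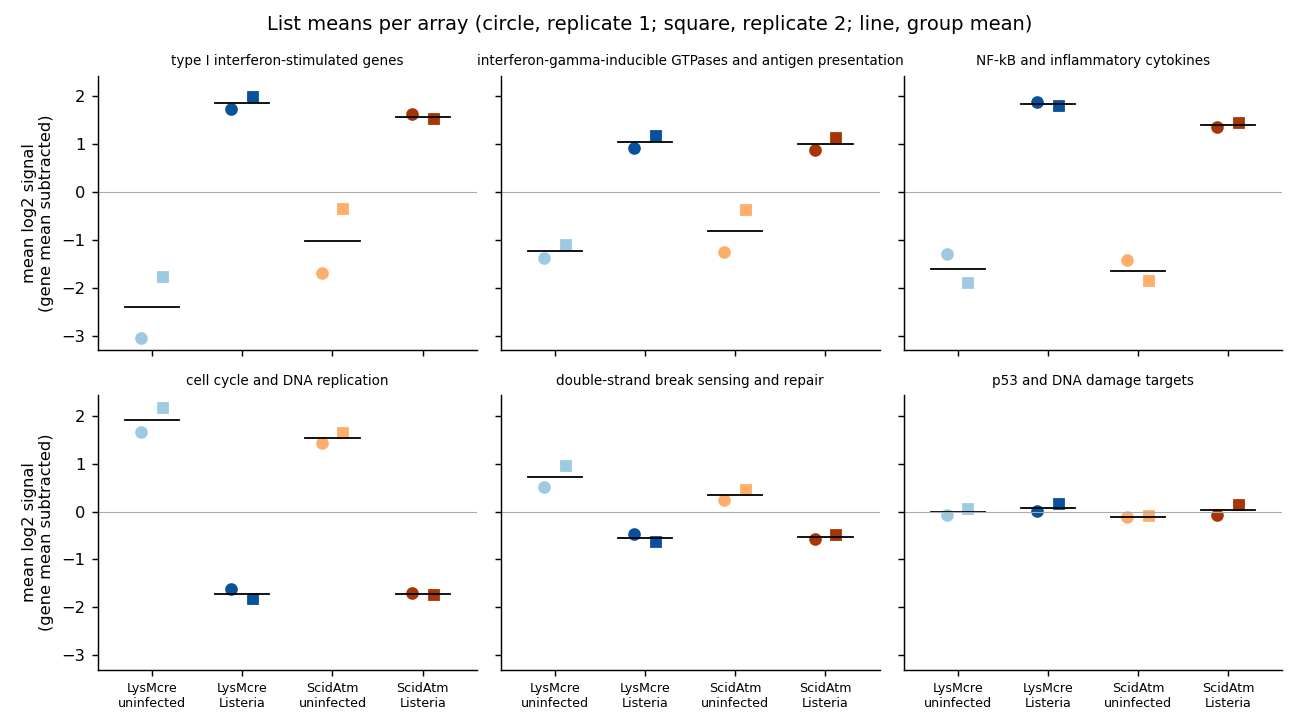
Mean log2 signal of the tested genes of 6 fixed lists on each array after subtracting each gene's mean over the 8 arrays; circles are replicate 1, squares replicate 2 and lines group means (n = 2). Interferon-stimulated genes range from -3.05 to -0.35 over the 4 uninfected arrays and from 1.52 to 1.98 over the 4 infected ones.

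In infected cultures the genotypes differed in no gene that passed. Clec16a stood at 1.88 ± 0.20 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0697, n = 2 per group). Ppp2r1b, not above background in infected LysMcre cultures, stood at least 8.19-fold above them in ScidAtm (adjusted p = 0.0697, and 0.035 without either ScidAtm uninfected array). Ifnb1 stood at -2.58 ± 0.32 (adjusted p = 0.124), Marco at -2.16 ± 0.34 and Atm at -1.57 ± 0.25 (adjusted p = 0.315 each). Ccl3 stood at -1.30 ± 0.22 (adjusted p = 0.322) and Nos2 at -1.26 ± 0.24 (adjusted p = 0.484). limma called 0 genes, with 429 at an unadjusted p under 0.05 against 413.5 by chance.

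NF-kB and inflammatory cytokine genes were placed lower in infected ScidAtm cultures, with 30 of 40 values negative and a median of -0.47 (camera adjusted p = 6.02e-07; adjusted p = 0.436 with an estimated correlation). No member passed over all genes, and adjusted over the list alone Csf3 was higher (0.85 ± 0.19) and Ccl3 lower. Type I interferon-stimulated genes were negative in 32 of 36 cases with a median of -0.20, or -0.03 under median scaling (adjusted p = 0.00504; adjusted p = 0.975 with an estimated correlation). None of them passed by either adjustment. Apoptosis and survival genes were negative in 17 of 25 cases with a median of -0.18, or -0.01 under median scaling (adjusted p = 0.00504; adjusted p = 0.399 with an estimated correlation). Pim2, a survival kinase gene on the X chromosome that was not above background in infected ScidAtm cultures, was the only one of them to pass adjusted over the list alone. The last 2 lists lost their calls without LysMcre infected array 2 (0.251 and 0.124) or ScidAtm infected array 2 (0.141 and 0.0999), and fry called none of the 3. The other 17 lists were not called, although Marco, Nos2 and Atm each passed as lower adjusted over its own list alone. H2-DMa, Slc7a5, Xrcc4, Csf3 and Pim2 were named after their values had been seen.

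**Figure D4:**
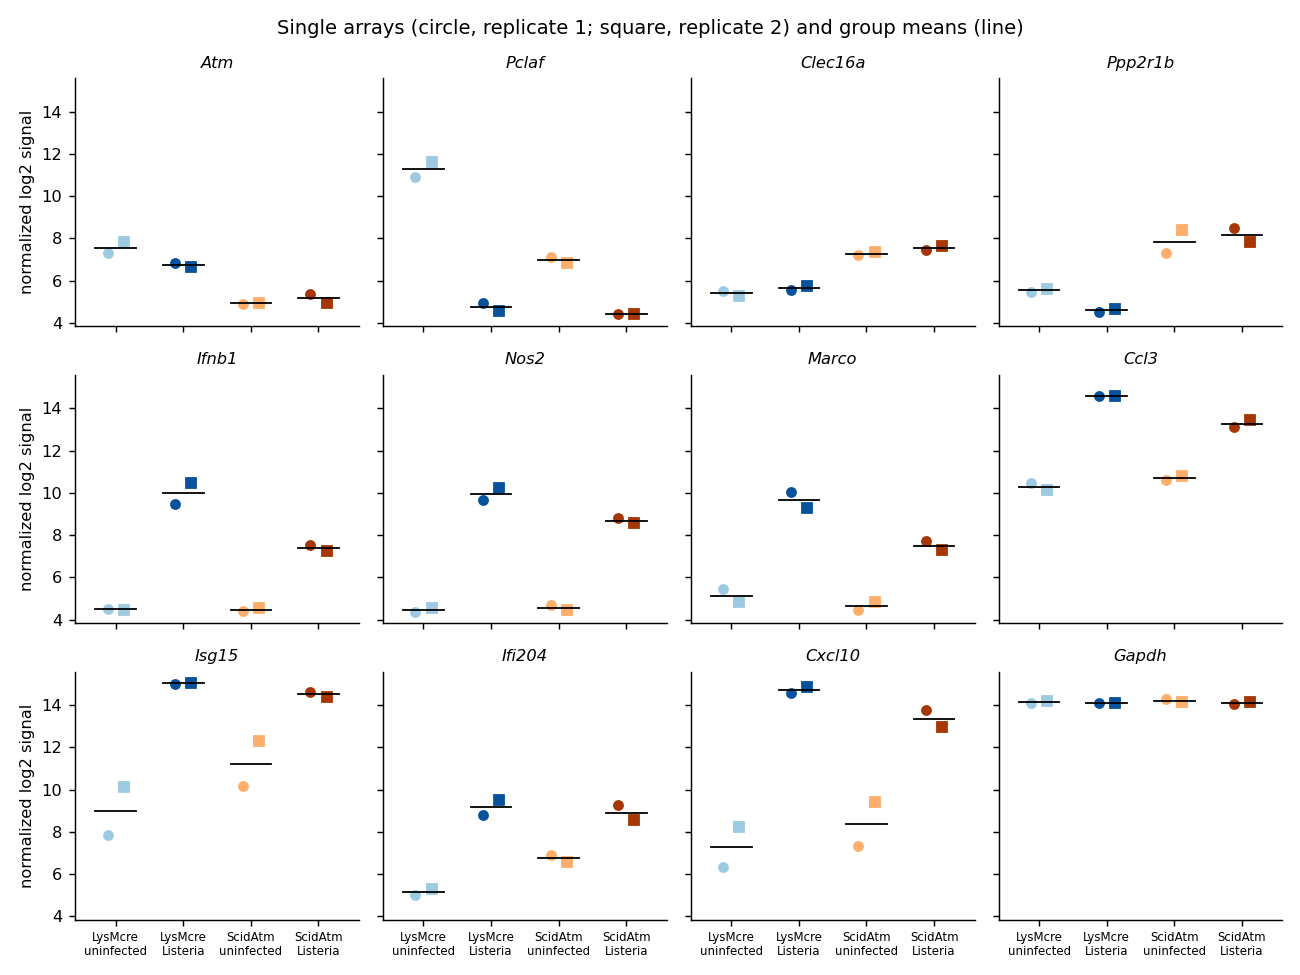
Normalized log2 signal of 12 genes on each array (vertical axis); circles are replicate 1, squares replicate 2 and lines group means (n = 2). Atm lies between 6.63 and 7.82 on the LysMcre arrays and between 4.92 and 5.38 on the ScidAtm arrays.

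Averaged over treatments, 4 genes differed between genotypes. Clec16a (1.88 ± 0.14) and Ppp2r1b were higher in ScidAtm, and Atm (-2.09 ± 0.18) and Pclaf were lower (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0115 for Ppp2r1b and 0.0083 for the others, n = 4 arrays per genotype). The fit took these arrays as independent. In LysMcre the Xist signal followed the replicate number, so uninfected and infected cultures of a number may share a mouse, which the labels do not state. The number of mice may then be smaller than the number of arrays. Ppp2r1b was not above background in infected LysMcre cultures and Pclaf was not in infected cultures of either genotype, so their averaged differences have no exact size, and for Pclaf the call rests on the uninfected cultures. Atm lies on chromosome 9 at 53437122 to 53536828, Pclaf on chromosome 9 at 65890323 to 65903551 and Ppp2r1b on chromosome 9 at 50856896 to 50899325. Clec16a lies on chromosome 16 at 10545309 to 10744878 and Prkdc on chromosome 16 at 15637444 to 15842239. Ppp2r1b is thus 2.54 Mb and Pclaf 12.4 Mb from Atm, and Clec16a 4.89 Mb from Prkdc. Pdxdc1 (-1.27 ± 0.18, adjusted p = 0.145) did not pass. Neither did Kif23 (adjusted p = 0.131), the kinase gene Sik2 (adjusted p = 0.145), Mns1 (adjusted p = 0.206) and Calml4 (adjusted p = 0.237), each not above background in at least 1 group. In all, 371 genes had an unadjusted p under 0.05, against 413.5 by chance. The 4 calls fell to 0 without any 1 of the 4 infected arrays and to 2 without ScidAtm uninfected array 2. Atm also lost its call without ScidAtm uninfected array 1 (0.0553), and Ppp2r1b without LysMcre uninfected array 1 (0.0604) or 2 (0.0624). With the mean of probes Clec16a fell to 0.78 (adjusted p = 0.684), and with no detection filter Ppp2r1b did not pass (0.0639).

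**Figure D5:**
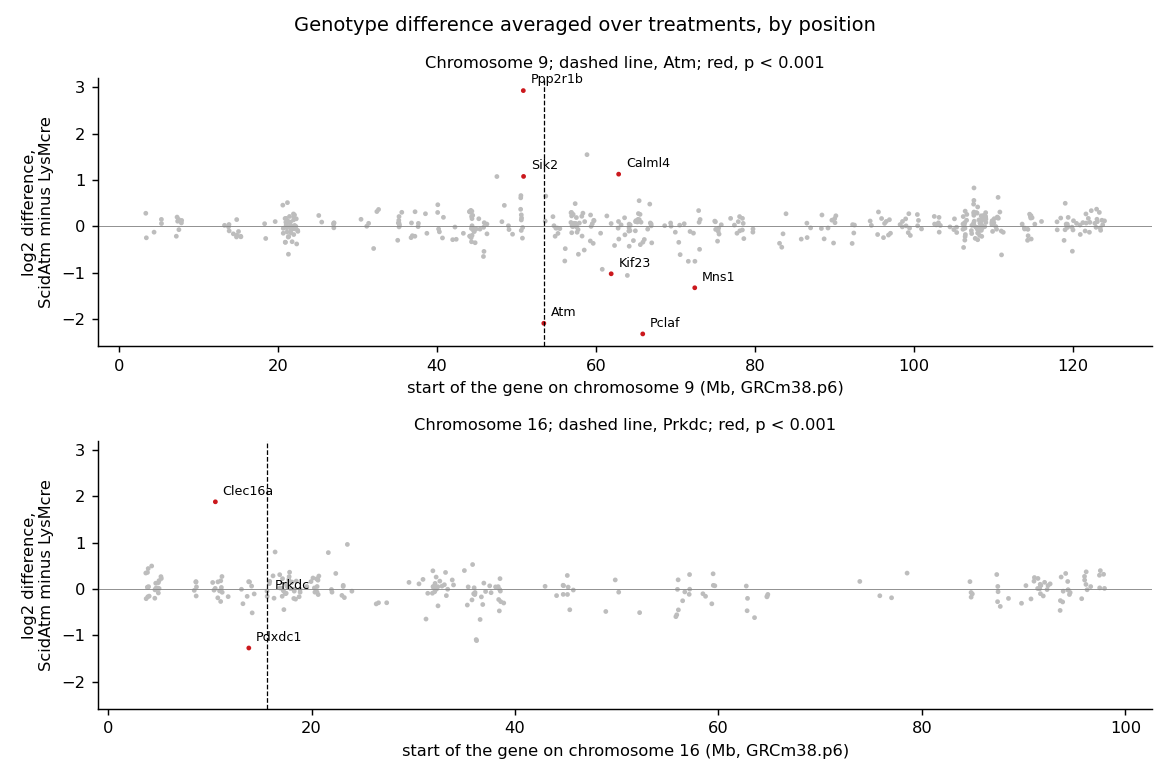
Genotype difference averaged over treatments (log2, ScidAtm minus LysMcre, vertical) of each tested gene against its start in Mb on chromosomes 9 and 16 (GRCm38.p6); dashed lines mark Atm and Prkdc and red points have an unadjusted p under 0.001. Clec16a and Ppp2r1b lie above 0 and Atm and Pclaf below; Ppp2r1b and Pclaf are drawn at values that include arrays at background.

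Camera called 6 lists in the averaged comparison, and none of them was called in the same direction in both treatments. The type I interferon average pools opposite directions, since that list was placed higher in uninfected and lower in infected ScidAtm cultures. Interferon-gamma, macrophage identity, cell cycle and double-strand break lists were called in uninfected cultures only, and the NF-kB list in infected cultures only. Type I interferon genes were placed higher (adjusted p = 1.69e-08; adjusted p = 0.769 with an estimated correlation), a call lost without ScidAtm uninfected array 2 (0.054). Interferon-gamma-inducible genes were placed higher (adjusted p = 0.00219; adjusted p = 0.802 with an estimated correlation), lost under median scaling (0.198) and without LysMcre uninfected array 1 (0.0828), LysMcre infected array 1 (0.151) or ScidAtm uninfected array 2 (0.804). Macrophage identity genes were placed higher (adjusted p = 0.0424; adjusted p = 0.561 with an estimated correlation), lost under median scaling (0.244). The macrophage call also ended without LysMcre uninfected 2 (0.214) or infected 1 (0.171), ScidAtm uninfected 1 (0.102) or 2 (0.077) or ScidAtm infected 1 (0.328). NF-kB genes were placed lower (adjusted p = 8.41e-05; adjusted p = 0.561 with an estimated correlation), lost without LysMcre uninfected array 1 (0.122). Cell cycle genes were placed lower (adjusted p = 0.000578; adjusted p = 0.769 with an estimated correlation), lost without LysMcre uninfected 2 (0.318), LysMcre infected 1 (0.0677) or ScidAtm uninfected 1 (0.102). Double-strand break genes were placed lower, with a median of -0.10, or 0.17 under median scaling (adjusted p = 0.0207; adjusted p = 0.769 with an estimated correlation). That call was lost without LysMcre uninfected 2 (0.566), LysMcre infected 1 (0.171), ScidAtm uninfected 1 (0.303) or ScidAtm infected 1 (0.0902). The double-strand break list was not tested without the altered genes Atm and Prkdc, so its lower placement partly reflects Atm itself. Atm was the only member of the 6 lists that passed over all genes, and adjusted over the list alone Marco, chosen here after its value was seen and not above background in uninfected ScidAtm cultures, was lower as well. Fry called none of the 6.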

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

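The tests that weigh explanations were chosen after the results had been seen, apart from the count of other splits of the arrays, and the interaction tests were planned. The windows other than the first, the tightened rule for further probes, the test on the remaining genes near the alleles and the comparison with differences between cultures came later still.

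Lists whose infection change differed between genotypes by the interaction test in camera are collected here with their mean interaction. The mean was -1.67 for type I interferon-stimulated genes, -0.46 for interferon-gamma-inducible genes, -0.40 for NF-kB genes, -0.23 for apoptosis genes, -0.20 for lysosome genes and -0.16 for migration genes. It was 0.41 for double-strand break genes and 0.38 for cell cycle genes. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.405. That setting also held 0 of the 12 lists called after infection in LysMcre and 0 of the 10 in ScidAtm. Failing it therefore does not set the interaction lists apart from those. For the type I interferon list the mean signal in ScidAtm minus LysMcre was 1.35 and 1.42 in uninfected cultures numbered 1 and 2. With infection it was -0.10 and -0.46. This interaction thus largely restates the difference between uninfected cultures, as do those of the interferon-gamma, cell cycle and double-strand break lists. The NF-kB one largely restates that between infected cultures. A second result lay outside the genes compared: among 705 probes without a gene name that passed the detection filter, infection changed 257 in LysMcre (133 higher and 124 lower, 36.5%) and 175 in ScidAtm (87 and 88, 24.8%). limma called 0 of them in the other 4 comparisons.

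Of 12 genes with an unadjusted p under 0.001 in the averaged comparison (8.26 by chance), Atm and Prkdc left out, 8 lay within 20 Mb of either, as did 311 of 8264 tested genes (3.76%; Fisher's exact two-sided p = 1.6e-09), a count that states the pattern and tests no explanation of it. The window had been set after the positions were seen, with Mns1 18.9 Mb from Atm just inside, and windows of 5, 10 and 40 Mb held 4, 6 and 8 of the 12 (Fisher's exact p = 1.56e-05, 8.7e-08 and 3.35e-08). With those genes left out, 10.2% of the 303 remaining genes in the window had an unadjusted p under 0.05 against 4.11% elsewhere, a share at percentile 99.93 of 10000 random pairs of windows on other chromosomes, so DNA carried along from another mouse strain with the alleles may account for part of the genotype differences. A base difference under a probe stays open, since only 2 of the 8 genes had further detected probes, of which 3 did not follow the first (Clec16a -0.33, Pdxdc1 0.50 and 1.83). In splits of the arrays within treatment, 6 of 18, the real one included, called at least as many genes as the 4 of the real split, and 18 are too few for a share under 0.05; each of the others that did so put the uninfected arrays numbered 1 on the same side, the highest calling 182, which points to a structure of the samples.

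Camera placed interferon-stimulated genes higher in uninfected ScidAtm cultures, although limma called 0 of the 36 over all genes and the list did not pass with an estimated correlation (adjusted p = 0.555) or in fry (adjusted p = 0.658). The difference in the list's score was 1.35 and 1.42 within the 2 replicate numbers, which occur once in each genotype, and 1.39 pooled. Uninfected culture 2 exceeded culture 1 by 1.27 in LysMcre and 1.34 in ScidAtm, nearly as much and in the same direction, but no label says that a number marks a shared preparation, so with 2 cultures per group differences between cultures cannot be told apart from the genotype. The list's median exceeded all of 10000 random lists matched on signal (percentile 100, highest 0.17), which argues against a general shift of genes of that brightness. Genotype and neighbouring DNA also stay open, untested for this list, and so does the sex of the mice. Without both LysMcre arrays numbered 2, which lacked Xist signal, camera still placed the list higher, but that rests on 1 uninfected LysMcre culture. The culture kept had the lower list score, -3.05 against -1.77, so the difference had to widen and this fit cannot test sex. The uninfected cultures numbered 1 both had Xist signal and differed by 1.35, with 1 culture per genotype.

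Infection changes were smaller in ScidAtm. Over genes selected by their ScidAtm call the slope of the LysMcre on the ScidAtm change was 1.11, above 1, which argues against selection of genes as the whole cause. Its SD of 0.0713 comes from 4 combinations of single cultures that were matched by replicate number and share arrays. It need not give the full spread. Over genes called in LysMcre the slope of the ScidAtm change was 0.817 without the members of both interferon lists, against 0.803 with them. The higher of the slopes under median scaling and the series matrix values, themselves read as quantile-normalized, was 0.838. Picking genes by their LysMcre change can by itself bring such a slope below 1. These values therefore cannot exclude the interferon genes alone or the normalization as the cause. Without both LysMcre arrays numbered 2, which lacked Xist signal, the slope was 0.824, but it rests on 1 LysMcre culture per treatment and on the genes called in that fit, so it does not exclude the sex of the mice. The genotype, the bacterial load, which was not measured in the data used here, the sex of the mice and differences between cultures remain open and could each contribute.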

How the results depend on the processing

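The fit leaving out both LysMcre arrays numbered 2 and the replicate number as a block within each treatment were chosen after seeing the data. Across the alternatives both infection counts stayed within 1.5 times their reported values except where stated, and the reported directions of the called genes named in the text were kept in each alternative that tested them. Leaving out both LysMcre arrays numbered 2 gave 866 calls for infection in LysMcre and 0 for genotype in uninfected cultures and averaged.

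Leaving out each array in turn gave 1528 to 3160 calls for infection in LysMcre (1528 without LysMcre infected array 2, 1507 of them shared with the reported calls), 921 to 2206 in ScidAtm, 0 to 1 for genotype in infected cultures, 0 to 1 in uninfected cultures, 0 to 1 for the interaction and 0 to 4 for genotype averaged. The lone array left in a group was assumed to vary like the other groups, and fewer arrays leave fewer degrees of freedom. The called lists numbered 33 to 45 against 44 and the slope of the infection responses 0.754 to 0.836 against 0.803.

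Genotype calls in infected cultures numbered 1 with the replicate number as a block within each treatment and 2 at an adjusted p under 0.1. In uninfected cultures they numbered 1 with no background correction, with no detection filter, with the mean of probes and with a replicate block, 28 with the block within each treatment and 0 with only the groups compared. The interaction gave 1 call with an offset of 50, 3 with the block within each treatment and 1 at an adjusted p under 0.1, and the averaged comparison 0 with no background correction. The labels do not say that a replicate number marks a shared mouse or preparation, so the numbers were not read as pairs. The correlation between groups of the deviation by number was 0.581 for the uninfected groups, whose same-numbered cultures thus deviated together, and between 0.00492 and 0.147 otherwise. The replicate block gave 3230, 2421, 0, 1, 0 and 4 calls in the 6 comparisons. Among named genes that had not passed, Nlrp3 (0.0378), Cdkn1a (0.00515) and Slc7a5 (0.00951) after infection in LysMcre and Tnf in ScidAtm (0.025) passed with it, and with the block within each treatment so did Mdm2 (0.0178) and Xrcc4 (0.0408) after infection in ScidAtm, Isg15 (0.0113), Mns1 (0.0317), Ppp2r1b (0.0450) and Kif23 (0.0496) between uninfected genotypes, Ppp2r1b in infected cultures (0.0490) and Isg15 and Pclaf in the interaction (0.0417 each). The cause was not tested.

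Camera with an estimated correlation called 0 lists in place of 44. The direction of 2 interaction lists turned: cell cycle leaving out both LysMcre arrays numbered 2 (0.829), and lysosome leaving out both (0.777) and without LysMcre uninfected array 2, where leaving out single arrays gave 1.05e-05 to 0.772. The cause was not tested. A slide block was not run because the files name no slide. Genes near background, Prkdc among them, limit what the signal can show.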

Other observations

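The families reported here were defined by gene symbol after the data had been seen, and their tests were chosen then. Of 11 such families 7 had at least 5 tested genes.

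Ribosomal protein genes fell after infection in 50 of 56 cases in LysMcre and 1 rose, with a median of -1.15 (camera adjusted p = 1.51e-13; adjusted p = 0.259 with an estimated correlation). In ScidAtm 39 fell and 1 rose, with a median of -0.92 (adjusted p = 2.34e-13; adjusted p = 0.263 with an estimated correlation). Histone genes, near-identical copies whose probes cannot be assigned with certainty, fell in 26 of 45 cases in LysMcre (adjusted p = 2.28e-06; adjusted p = 0.259 with an estimated correlation). In ScidAtm 20 fell and 3 rose, with 0 higher under median scaling (adjusted p = 4.57e-05; adjusted p = 0.263 with an estimated correlation). Mcm, Ncap and Smc genes, which belong to the replicative helicase, condensin, cohesin and the Smc5/6 complex, fell in 13 of 18 cases and rose in 2 in LysMcre (adjusted p = 2.12e-05; adjusted p = 0.259 with an estimated correlation), against 12 and 2 in ScidAtm (adjusted p = 4.57e-05; adjusted p = 0.263 with an estimated correlation).

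Proteasome genes rose in 12 of 40 cases and fell in 2 in LysMcre (adjusted p = 0.000172; adjusted p = 0.267 with an estimated correlation), led by the immunoproteasome genes Psmb9 (1.85), Psmb8 (1.67) and Psmb10 (1.55). Psmb8 did not pass without LysMcre infected array 1 (adjusted p = 0.0515), and neither it nor Psmb9 did without both LysMcre arrays numbered 2 (0.0872 and 0.0545). In ScidAtm 5 rose and 1 fell (adjusted p = 0.00637; adjusted p = 0.377 with an estimated correlation). Kinesin genes fell in 9 of 22 cases and rose in 3 in LysMcre (adjusted p = 0.0346; adjusted p = 0.259 with an estimated correlation), against 10 and 4 in ScidAtm (adjusted p = 0.00667; adjusted p = 0.263 with an estimated correlation). Heat shock and Trim genes were not called in LysMcre (adjusted p = 0.698 and 0.0887) or ScidAtm (0.777 and 0.132).

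Between uninfected genotypes no member of these families passed, but camera placed 6 of the 7 apart from other genes and none with an estimated correlation. Lower in ScidAtm were histone genes (median -0.33; adjusted p = 9.6e-07; adjusted p = 0.276 with an estimated correlation), Mcm, Ncap and Smc genes (median -0.26, or 0.05 under median scaling; adjusted p = 0.0149; adjusted p = 0.495 with an estimated correlation) and ribosomal protein genes (median -0.10, or 0.12 under median scaling; adjusted p = 0.0213; adjusted p = 0.612 with an estimated correlation). Kinesin genes were also placed lower (median -0.15, or 0.10 under median scaling; adjusted p = 0.0409; adjusted p = 0.276 with an estimated correlation). Proteasome genes (median 0.06; adjusted p = 0.612 with an estimated correlation) and Trim genes (median 0.15; adjusted p = 0.476 with an estimated correlation) were placed higher (adjusted p = 0.0409 each), and heat shock genes were not called (adjusted p = 0.635). In infected cultures camera called none of the 7 between genotypes (smallest adjusted p = 0.222).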
